A study of Homo sapiens with 6 samples.

How the data were processed

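Poly(A) RNA of HepG2 cells carrying the doxycycline-inducible construct pInducer20-RNF125 was sequenced after 48 h without doxycycline (Cont, 3 libraries) or with 2 µM doxycycline (Dox, 3 libraries), per the labels. Cells were grown in low-glucose DMEM and RNA was extracted with RNAiso Plus. The 6 libraries are the whole series as analysed, and none came from doxycycline-treated cells without the insert.

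The deposited table holds log2 values, the authors' log2 of FPKM (fragments per kilobase of gene, scaled to library size), for 11775 genes, with 1 column per library. The authors' notes name FastQC 0.11.7 for read quality and the genome build GRCh38. The aligner, the counting tool, the annotation, the normalization and the gene filter are not given in the sources used here. The base of the logarithm was checked with the union exon lengths of GENCODE release 29: 2 to the power of the values times length in kb summed to 978791 in Cont 1 and 996129 in Cont 2, close to the total to which FPKM scales a library, against 1.06e+07 and 1.24e+07 for base e. For all 11726 genes with a length (49, or 0.416%, had none), the values of all 6 libraries went back to whole reads within 0.05 of a read after removal of a small offset, about 2 reads per library. The recovered totals give the depth of the listed genes. A gene's counting error follows from its reads: the 44 reads of RNF125 in Cont 1 have an exact 95% interval of 32.0 to 59.1 reads. Such intervals cover counting error only, since the reads carry no molecular identifiers.

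The design assumed FPKM on a linear scale, so the values were converted back to FPKM and fitted as log2(FPKM + 1), for the 10508 genes with a mean of at least 1 FPKM over the 6 libraries. Dox was compared with Cont with limma 3.58.1 in R 4.3.3, by its moderated test with eBayes and a trend of variance on level, two-sided. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The 3 Cont libraries formed one group and the 3 Dox libraries the other, with no further scaling and no block. The single comparison of RNF125 and of the mitochondrial share of reads used two-sided exact permutation tests. Tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.

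There were 45 gene lists, written before the data were examined, for the pathways and cell types that bear on HepG2 cells, RNF125, the signalling in the series title and the known effects of doxycycline. The 42 lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01 between genes, and again with the correlation estimated from the data and with fry. Adjusted p-values are Benjamini-Hochberg values over these lists. Some genes (45) are in more than 1 list. Intervals of medians are 95% bootstrap intervals over list members (10000 resamples). They treat members as independent and leave out the spread between libraries. Genes were named by a rule set before the data were examined: RNF125, the 10 largest rises and falls among called genes whose groups do not overlap, 6 genes of the series title's pathway, the reported RNF125 substrates, and, for each list past the list test or with at least 25% of its members called, up to 4 called members with the largest change. Some genes that this rule names are not reported here.

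The alternatives tried were other pseudocounts (0.1 and 0.5), no filter or a limit of 5 FPKM, rescaling to a common sum (TPM scale), median centring, quantile normalization, eBayes without a trend or robust, a replicate block, a 2-fold limit, an adjusted p under 0.01, other list tests, and leaving out each library in turn. Added after seeing the data were the deposited log2 values with no further pseudocount, limma's voom on the recovered reads, and rescaling to reads outside the mitochondrial genome. The fit was tested on simulated reads of 3 against 3 libraries, with 200 genes changed. It called 0 of 49 genes changed 1.1-fold, 10 of 50 changed 1.2-fold, 47 of 50 changed 1.5-fold and 48 of 48 changed 2-fold. It also called 4 of 10281 unchanged genes. Each gene took the median spread of genes at its level, and genes were drawn independently. Genes of unusual spread and effects shared within a library were absent, so this is not the rate of false calls in the data. In the same simulation voom called 25 of 50 genes changed 1.2-fold and 5 unchanged genes, and camera called 0 of 42 unchanged lists, whose genes were drawn at random without correlation between them, so this does not test lists of correlated genes. The 1267 genes under the FPKM limit were left out of the main test. Reads of the inserted RNF125 copy and of the cell's own gene, and reads shared between paralogs, could not be separated.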

Results

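The libraries came from HepG2, a human liver cancer cell line, carrying pInducer20-RNF125, a construct from which doxycycline switches on RNF125, an E3 ubiquitin ligase. Cells were kept for 48 h without doxycycline (Cont, 3 libraries) or with 2 µM of it (Dox, 3 libraries), and poly(A) RNA was sequenced. The stated purpose was to find which genes change in expression when RNF125 is induced. Values were given for 11775 genes as log2 FPKM. The whole reads behind them came to 18.8 M, 21.9 M and 24.5 M (M, mega) in Cont 1, 2 and 3 and to 19.3 M, 19.1 M and 18.8 M in Dox 1, 2 and 3. The labels do not say that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Over the 6 within-group pairs of libraries, the chi-square per gene had a median of 0.972 to 2.11 and a mean of 4.37 to 13.5. All of these lie above what counting error alone would give. The first principal component held 77.5% of the variance and separated Cont from Dox, and the second held 9.83% and set Dox 2 apart from Dox 1 and Dox 3. Mitochondrially encoded genes took 9.103% ± 1.202 of reads in Cont and 7.26% ± 0.84 in Dox (SD, n = 3 each; two-sided exact permutation p = 0.2, where 0.1 is the smallest possible).

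RNF125 was higher in every Dox library than in every Cont library, which checks the labels. It had 44, 57 and 67 reads in Cont 1, 2 and 3 against 1963, 2420 and 1905 reads in Dox 1, 2 and 3. Its level went from 0.404 ± 0.034 to 16.9 ± 2.1 FPKM (SD, n = 3 each), a 41.9-fold ratio of the group means, and its log2 fold change was 3.67 (SE 0.08) with a limma adjusted p of 2.92e-09. The two-sided exact permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. Because low levels are damped on the log2(FPKM + 1) scale, the fold change was 5.38 on the log2 FPKM values as deposited. The gene (ENSG00000101695.8) lies on chromosome 18, from 32018372 to 32073213 on the plus strand of GRCh38. Reads from the inserted copy and from the cell's own gene were not told apart in these values.

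**Figure D1:**
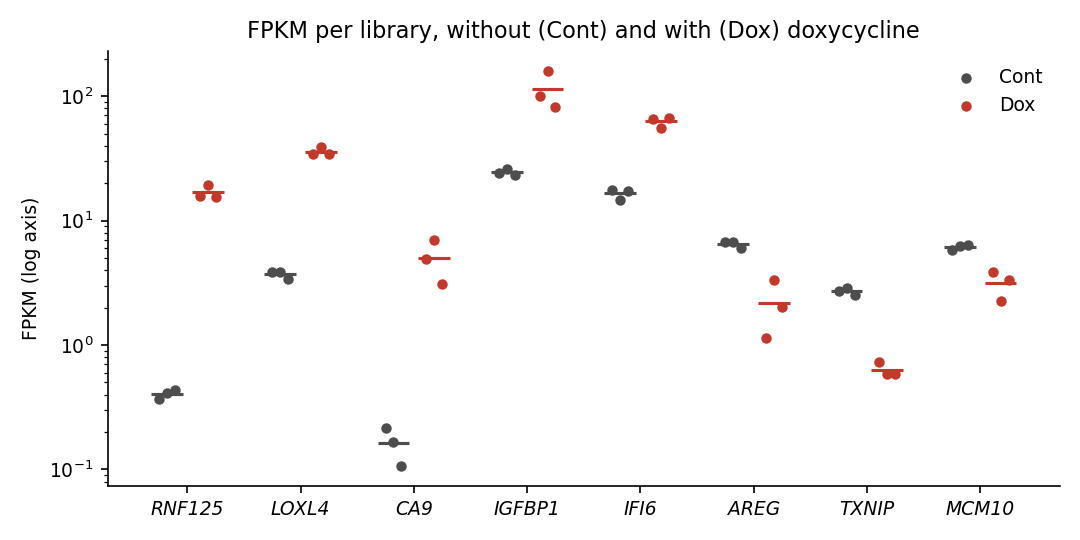
FPKM of 8 genes in each library on a log axis; dots are the 3 Cont (grey) and 3 Dox (red) libraries and lines their means. RNF125 went from a mean of 0.404 FPKM to 16.9 FPKM, and LOXL4, CA9, IGFBP1 and IFI6 were higher and AREG, TXNIP and MCM10 lower in all 3 Dox libraries than in all 3 Cont libraries.

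Doxycycline was followed by small changes in a large part of the measured genes and by large rises in a few. Genes are ranked here on the log2(FPKM + 1) scale, which damps changes at low levels. On that scale the largest rises after RNF125 were in LOXL4, a lysyl oxidase of the extracellular matrix (3.72 ± 0.26 to 35.8 ± 2.6 FPKM, log2 fold change 2.96 (SE 0.07)), and BIRC7, an inhibitor of apoptosis (1.53 ± 0.37 to 13.7 ± 0.96 FPKM, 2.55 (SE 0.10)). CA9, a carbonic anhydrase induced by hypoxia, went from 0.163 ± 0.054 to 4.99 ± 1.9 FPKM. CA9 had 11 reads over the 3 Cont libraries and 472 over the 3 Dox libraries, and the offset of about 2 reads per library in the deposited values raises its level in Cont. IGFBP1, a secreted binding protein of insulin-like growth factors, went from 24.5 ± 1.5 to 114 ± 41.2 FPKM. The apolipoprotein APOA4 went from 6.14 ± 0.57 to 29.7 ± 3.9 FPKM. The chemokine CCL20 went from 5.45 ± 0.34 to 26.9 ± 9.3 FPKM and the interferon-induced IFI6 from 16.5 ± 1.6 to 62.4 ± 6.3 FPKM. The hypoxia-responsive NDRG1 went from 2.02 ± 0.095 to 9.92 ± 2.9 FPKM and MAGEH1 from 1.15 ± 0.33 to 6.49 ± 0.55 FPKM. The adjusted p of these 10 rises was at most 3.21e-05. Among the falls were those of AREG and EREG, ligands of the EGF receptor, from 6.47 ± 0.41 to 2.16 ± 1.1 FPKM and from 1.99 ± 0.23 to 0.612 ± 0.298 FPKM. The steroid-metabolising aldo-keto reductase AKR1C2 fell from 38.2 ± 0.36 to 15.96 ± 1.4 FPKM and the complexin CPLX2 from 57.8 ± 1.2 to 24.6 ± 1.4 FPKM. TXNIP, which binds thioredoxin, fell from 2.695 ± 0.19 to 0.635 ± 0.088 FPKM. TUBA1A, an alpha-tubulin, fell from 4.71 ± 0.12 to 1.698 ± 0.27 FPKM, and the epithelial keratins KRT19 and KRT23 from 51.2 ± 2.4 to 26.8 ± 0.65 FPKM and from 27.7 ± 0.95 to 14.5 ± 2.1 FPKM. S100A3 (-1.01) and AKAP12 (-0.99) completed the 10 largest falls on that scale, whose adjusted p was at most 0.00053. The exons of CA9 and APOA4 overlapped those of other genes over 38.5% and 43.1% of their length.

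In all, 4753 of the 10508 genes tested (45.2%) passed limma's adjusted p of 0.05, 2393 of them higher and 2360 lower with Dox. Most changes were small: on the log2(FPKM + 1) scale, 4304 of the changed genes (90.6%) differed by less than 1.5-fold, and the median absolute log2 fold change among the changed genes was 0.29. Changes of at least 2-fold on that scale were found in 83 genes that were higher and 6 that were lower. On the deposited log2 FPKM scale, which damps low levels less, the corresponding counts among the same 4753 genes were 3995 (84.1%), 123 and 19. The 3 values of each group did not overlap in 5867 genes (55.8%), against 10% by chance. The split into higher and lower genes depended on the scaling: with libraries rescaled to the reads outside the mitochondrial genome, 2008 genes were higher and 2993 lower (40.2% higher, against 50.3%).

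**Figure D2:**
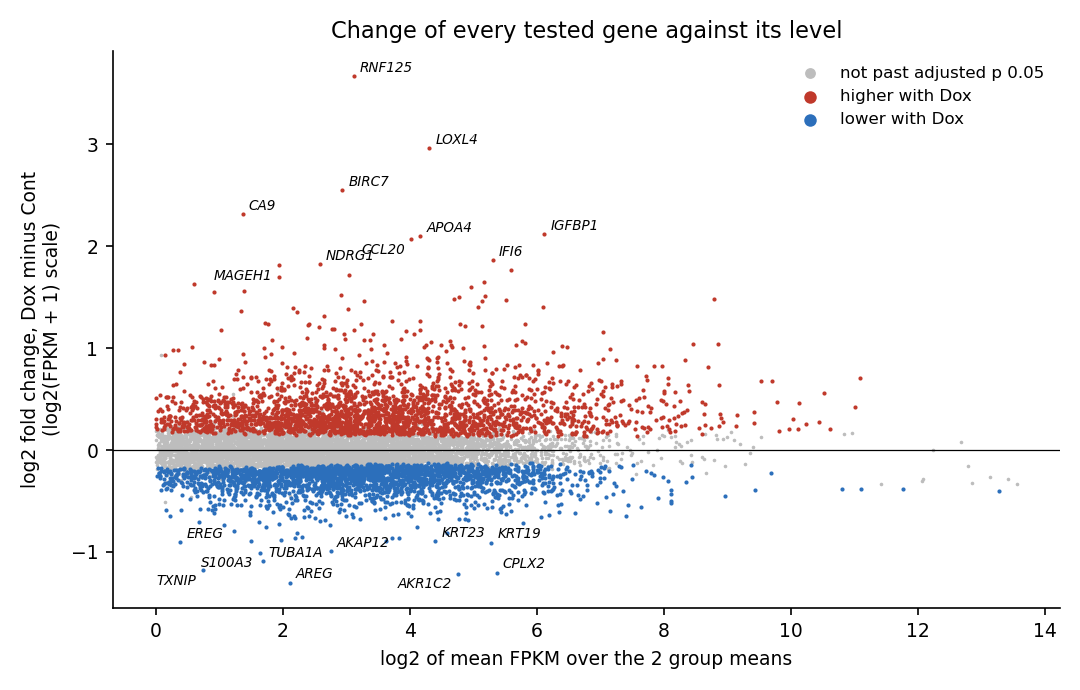
Each tested gene's log2 fold change (Dox minus Cont, log2(FPKM + 1) scale) against the log2 of its mean FPKM; red genes were higher and blue genes lower with Dox at an adjusted p under 0.05, and grey genes did not pass. RNF125 had the largest change (3.67), and the 4753 changed genes lay mostly close to 0.

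Of the 5 proteins reported as substrates of RNF125 and fixed as a list, the mRNA of IFIH1, the RNA sensor MDA5, rose from 1.25 ± 0.061 to 2.203 ± 0.075 FPKM (log2 fold change 0.51 (SE 0.06), adjusted p = 0.000149). The kinase JAK1 fell by 0.20 (adjusted p = 0.0108) and the adaptor MAVS by 0.21 (adjusted p = 0.0289). RIGI, which encodes the sensor RIG-I, had a log2 fold change of 0.05 (SE 0.07) and an adjusted p of 0.618, and TRIM14 one of -0.15 (SE 0.06) and an adjusted p of 0.0505. As a list the 5 did not pass (adjusted p = 0.791), with 1 higher and 3 lower when adjusted over the list alone. Protein levels of these substrates were not measured here. The MAVS call was lost without Cont 2, without Cont 3 or without Dox 1, with an adjusted p between 0.00481 and 0.124 over all alternatives. TRIM14 passed under 6 of 19 alternatives, over which its adjusted p ran from 0.0153 to 0.189. Among 17 genes of the RIG-I-like receptor pathway, 5 rose, 3 fell and 9 did not pass. 6 rose and 3 fell when adjusted over the list alone. DHX58, the related sensor LGP2, rose from 1.204 ± 0.15 to 2.53 ± 0.051 FPKM and the deubiquitinase CYLD from 1.43 ± 0.047 to 2.16 ± 0.25 FPKM, and TRAF3, a signalling adaptor, fell from 6.005 ± 0.28 to 4.603 ± 0.13 FPKM. The list did not pass (adjusted p = 0.919).

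Interferon-stimulated genes rose: of 33 tested, 20 rose, 0 fell and 13 did not pass. 20 rose and 1 fell when adjusted over the list alone. The largest changes on the log2(FPKM + 1) scale were in IFI6 and IFI27 (0.969 ± 0.24 to 4.08 ± 0.698 FPKM). ISG15, a ubiquitin-like modifier, went from 32.9 ± 0.702 to 78.9 ± 5.7 FPKM and IFIT1 from 0.655 ± 0.11 to 2.32 ± 0.202 FPKM. The median log2 fold change of the list was 0.26 (95% interval 0.13 to 0.47) and its camera adjusted p 1.13e-06, against an adjusted p of 0.569 with an estimated correlation. Among 11 NF-κB targets, CCL20 and IER3 (29.97 ± 2.6 to 48.4 ± 12.5 FPKM) rose and NFKB2 rose slightly (0.26), NFKB1 fell (-0.21) and 7 did not pass, with the same counts when adjusted over the list alone, and the list test gave an adjusted p of 0.457. The NFKB1 call was lost on the TPM scale and without Cont 1, Cont 3, Dox 1 or Dox 3 (adjusted p 0.00955 to 0.109 over the alternatives).

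The series concerns signalling from MET through mTORC2 and AKT to FOXO1 in liver cancer with mutated β-catenin. The genes of that pathway were therefore examined by name, at the level of mRNA only. Protein levels and phosphorylation were not measured here. MET, the receptor of hepatocyte growth factor, fell from 10.1 ± 0.55 to 8.22 ± 0.57 FPKM (adjusted p = 0.00683). CTNNB1, which encodes β-catenin, had a log2 fold change of -0.04 (SE 0.06) and an adjusted p of 0.607. The corresponding values were -0.06 (SE 0.07) and 0.496 for AKT1, 0.04 (SE 0.07) and 0.645 for MTOR, and 0.14 (SE 0.06) and 0.0874 for RICTOR, a subunit of mTORC2. RICTOR passed with voom on reads, and its adjusted p ran from 0.0352 to 0.273 over the alternatives. FOXO1 rose from 3.97 ± 0.36 to 4.74 ± 0.18 FPKM (adjusted p = 0.0275), a call lost without Cont 1, Cont 2, Dox 1 or Dox 2 and on rescaling to reads outside the mitochondrial genome (adjusted p 0.0201 to 0.0773 over the alternatives). Its log2 fold change of 0.21 was 0.15, 0.22, 0.21 and 0.19 without these libraries and 0.17 on that rescaling. FOXO3 rose from 4.35 ± 0.39 to 6.18 ± 1.2 FPKM, and GSK3B (-0.27) and PRR5 (-0.26), another mTORC2 component, fell. The GSK3B call was lost without Cont 3 (adjusted p = 0.0592, with a lowest of 0.00377 over the alternatives). Of the 20 genes in this list, 5 rose, 6 fell and 9 did not pass, and the list test gave an adjusted p of 0.997. 5 rose and 6 fell when adjusted over the list alone.

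Known FOXO targets changed in both directions. Among the 15 tested, 7 rose, 2 fell and 6 did not pass. 7 rose and 3 fell when adjusted over the list alone. IGFBP1, CITED2, a transcriptional coactivator (6.23 ± 0.24 to 14.4 ± 2.5 FPKM), and the repressor BCL6 (5.24 ± 0.074 to 7.87 ± 0.83 FPKM) rose, and TXNIP fell. The list did not pass (median 0.25 (95% interval -0.04 to 0.41), adjusted p = 0.108). It passed with genes of at least 5 FPKM alone (adjusted p = 0.0348) and without Dox 3 (0.046). Its adjusted p reached 0.147 over the alternatives, and its median without Dox 2 was 0.10. Among 20 β-catenin targets, 8 rose, 6 fell and 6 did not pass, with a list test adjusted p of 0.997. 8 rose and 6 fell when adjusted over the list alone. CCND1, which encodes cyclin D1, fell from 56.1 ± 2.2 to 38.6 ± 1.2 FPKM. The Wnt-responsive receptor LGR5 rose from 21.3 ± 0.96 to 30.8 ± 0.65 FPKM and the transporters SLC1A2 and SLC13A3 from 1.53 ± 0.065 to 2.51 ± 0.065 FPKM and from 10.5 ± 0.29 to 14.5 ± 0.598 FPKM.

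Genes of DNA replication and mitosis fell. Of 41 genes of DNA replication and of E2F control, 0 rose, 40 fell and 1 did not pass. 0 rose and 40 fell when adjusted over the list alone. UHRF1, which maintains DNA methylation at replication forks, fell from 30.9 ± 0.52 to 17.3 ± 3.2 FPKM. The replication initiation factor MCM10 fell from 6.18 ± 0.295 to 3.14 ± 0.83 FPKM, the checkpoint mediator CLSPN from 4.43 ± 0.44 to 2.22 ± 0.27 FPKM and DTL from 8.06 ± 0.45 to 4.63 ± 0.297 FPKM. The median log2 fold change was -0.46 (95% interval -0.54 to -0.35). The list had a camera adjusted p of 8.22e-14 and an adjusted p of 0.569 with an estimated correlation. Of 39 mitotic genes, 1 rose, 28 fell and 10 did not pass. 1 rose and 28 fell when adjusted over the list alone. The proliferation marker MKI67 fell from 20.04 ± 2.5 to 12.4 ± 1.1 FPKM. The mitotic kinase PLK1 fell from 39.9 ± 1.7 to 27.3 ± 2.1 FPKM and the spindle factor TPX2 from 61.2 ± 3.7 to 43.3 ± 2.6 FPKM. That list had a median of -0.31 (95% interval -0.37 to -0.24). It had a camera adjusted p of 4.59e-07 and an adjusted p of 0.699 with an estimated correlation and of 0.0517 with fry. Both lists lay lowest in Dox 2, where the mean over the replication genes was 0.61 below Cont against 0.37 in Dox 1 and 0.39 in Dox 3. In the fit without Dox 2, 38 of 41 replication genes and 26 of 39 mitotic genes fell, 0 and 2 rose. The p53 targets changed in both directions: of 25, 7 rose, 7 fell and 11 did not pass (list test adjusted p = 0.997). 7 rose and 7 fell when adjusted over the list alone. The cytokine GDF15 rose from 224 ± 7.1 to 479 ± 166 FPKM and BBC3, the pro-apoptotic PUMA, from 7.62 ± 0.51 to 13.5 ± 1.8 FPKM. GDF15 is also in the list of ATF4 targets described below, and was at 367, 670 and 400 FPKM in Dox 1, 2 and 3. BTG2, an antiproliferative gene, fell from 10.8 ± 0.34 to 7.02 ± 0.78 FPKM. Of 26 apoptosis regulators, 5 rose, 5 fell and 16 did not pass (list test adjusted p = 0.756). 5 rose and 5 fell when adjusted over the list alone.

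Targets of hypoxia-inducible factor (HIF) had the largest median rise among the lists. Of 21, 16 were higher, 0 lower and 5 not past the test, and 16 were higher when adjusted over the list alone. Beside CA9 and NDRG1, DDIT4, an inhibitor of mTORC1, rose from 16.7 ± 1.01 to 53.8 ± 33.97 FPKM. DDIT4 is also in the ATF4 list below, and was at 35.6, 93.0 and 32.9 FPKM in Dox 1, 2 and 3. The median was 0.80 (95% interval 0.42 to 1.07). The camera adjusted p was 4.65e-08 and the adjusted p with an estimated correlation 0.569. Glycolysis genes did not move together, since 5 rose, 5 fell and 11 did not pass, of 21 (list test adjusted p = 0.997). 5 rose and 6 fell when adjusted over the list alone. The regulators PFKFB3 (1.82 ± 0.196 to 5.27 ± 2.6 FPKM) and PFKFB4 (2.77 ± 0.12 to 5.63 ± 0.602 FPKM) and the hexokinase HK2 (13.7 ± 0.63 to 22.1 ± 3.6 FPKM) rose. PFKP, the platelet form of phosphofructokinase, fell (2.49 ± 0.32 to 1.27 ± 0.0057 FPKM). Targets of ATF4, the transcription factor of the integrated stress response, rose, with 26 higher, 2 lower and 9 not past the test, of 37. 26 rose and 2 fell when adjusted over the list alone. DDIT3, which encodes CHOP, went from 12.1 ± 0.52 to 39.9 ± 24.95 FPKM and CTH, an enzyme of cysteine synthesis, from 3.07 ± 0.084 to 8.797 ± 3.7 FPKM. This list had a median of 0.38 (95% interval 0.27 to 0.65). It had a camera adjusted p of 5.59e-06 and an adjusted p of 0.699 with an estimated correlation and of 0.0849 with fry. Of 25 genes of the unfolded protein response of the endoplasmic reticulum, 21 rose, 0 fell and 4 did not pass. 23 rose and 0 fell when adjusted over the list alone. HERPUD1 and SYVN1, components of protein degradation at the endoplasmic reticulum, rose from 17.6 ± 0.79 to 55.2 ± 24.6 FPKM and from 9.73 ± 0.32 to 17.98 ± 2.4 FPKM and the chaperone DNAJB9 from 10.3 ± 0.92 to 25.4 ± 9.8 FPKM. The list median was 0.37 (95% interval 0.30 to 0.45). Its camera adjusted p was 2.43e-08, and 0.569 with an estimated correlation.

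Dox 2 stood apart in these stress lists. DDIT3 was at 24.9, 68.7 and 26.1 FPKM in Dox 1, 2 and 3, and the mean over the ATF4 targets lay 0.27, 0.82 and 0.34 above Cont in log2 units. The corresponding means were 0.77, 1.09 and 0.63 for the HIF targets and 0.37, 0.60 and 0.36 for the unfolded protein response. In the fit without Dox 2, 16 HIF targets were higher and 1 lower, 26 ATF4 targets were higher and 2 lower, and 20 genes of the unfolded protein response were higher and 0 lower. The exons of DDIT3 and DDIT4 overlapped those of other genes over 39.6% and 41.2% of their length. Immediate early genes, which respond to growth factors and stress, also rose: of 21, 11 rose, 1 fell and 9 did not pass. 11 rose and 1 fell when adjusted over the list alone. The phosphatase DUSP1 went from 14.7 ± 1.3 to 47.4 ± 13.3 FPKM, EGR1 from 4.68 ± 0.25 to 14.8 ± 3.2 FPKM and JUNB from 9.27 ± 0.98 to 16.5 ± 1.2 FPKM. ATF3 rose by 0.94, and by 0.55 without Dox 2, and its call was lost with robust eBayes, as was that of DDIT4 (highest adjusted p 0.0844 and 0.051). The list had a camera adjusted p of 0.00534 and an adjusted p of 0.764 with an estimated correlation and of 0.0832 with fry. Its median of 0.20 was 0.34 without Dox 1 and 0.13 without Dox 2. In the fit without Dox 2, 10 immediate early genes were higher and 4 lower. Among 33 lysosome and autophagy genes, 7 rose, 5 fell and 21 did not pass (list test adjusted p = 0.997). 7 rose and 5 fell when adjusted over the list alone. The autophagy genes ULK1 (6.78 ± 0.45 to 13.1 ± 2.05 FPKM) and WIPI1 (6.47 ± 0.597 to 11.4 ± 1.1 FPKM) rose. Of 15 YAP/TAZ targets, 6 rose, 2 fell and 7 did not pass (list test adjusted p = 0.422), with CCN2 higher (24.9 ± 1.3 to 48.1 ± 11.04 FPKM) and FJX1 lower (2.48 ± 0.201 to 1.33 ± 0.24 FPKM). 6 rose and 2 fell when adjusted over the list alone.

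**Figure D3:**
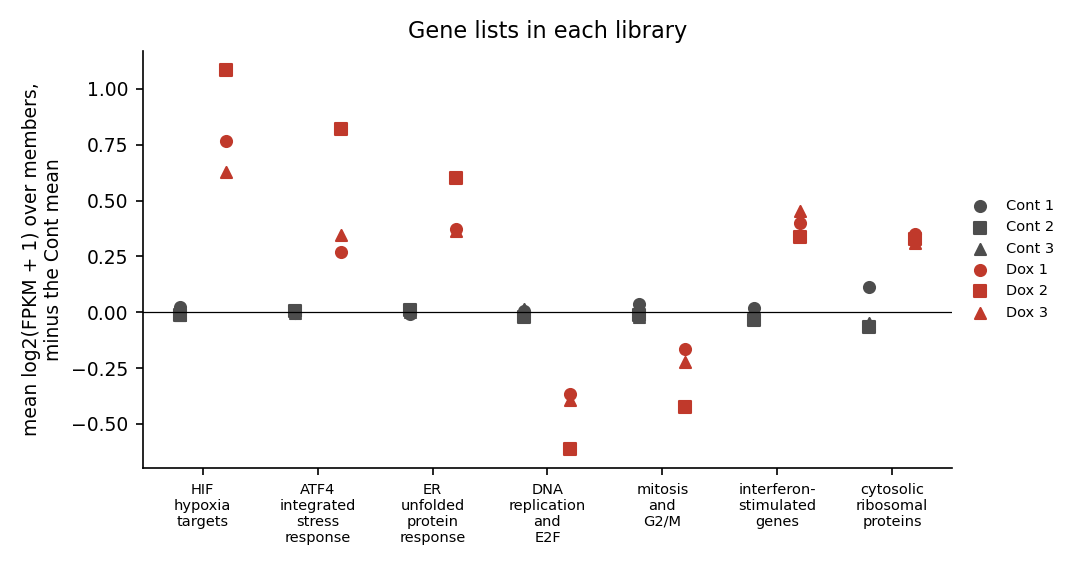
Mean log2(FPKM + 1) over the members of 7 gene lists in each library, minus the mean of the 3 Cont libraries (grey symbols, Cont; red symbols, Dox; circle, square and triangle, libraries 1, 2 and 3). Dox 2 lay apart from Dox 1 and Dox 3 for the HIF, ATF4 and unfolded protein response lists (1.09, 0.82 and 0.60) and for the replication and mitosis lists.

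Genes for proteins that hepatocytes secrete rose. Of 29 plasma protein genes, 23 rose, 0 fell and 6 did not pass. 24 rose and 0 fell when adjusted over the list alone. Beside APOA4, ITIH3, an inter-alpha-trypsin inhibitor chain, rose from 18.05 ± 1.01 to 49.3 ± 3.4 FPKM. SERPINA7, the thyroxine-binding globulin, rose from 37.5 ± 2.3 to 62.1 ± 1.8 FPKM and APOA1, the main apolipoprotein of high-density lipoprotein, from 1662 ± 84.8 to 2714 ± 182 FPKM. The median was 0.28 (95% interval 0.21 to 0.43). The camera adjusted p was 9.82e-09, and 0.569 with an estimated correlation. Of 28 complement and coagulation genes, 19 rose, 0 fell and 9 did not pass. 21 rose and 0 fell when adjusted over the list alone. Coagulation factor F7 rose from 6.27 ± 0.42 to 11.3 ± 1.02 FPKM and SERPINF2, which inhibits plasmin, from 205 ± 8.4 to 308 ± 12.7 FPKM. C4A, a near copy of C4B, rose from 19.1 ± 1.9 to 28.8 ± 2.7 FPKM. The list median was 0.29 (95% interval 0.18 to 0.38). Its camera adjusted p was 7.53e-07, and 0.29 with an estimated correlation. With quantile normalization the log2 fold change of SERPINF2 was 0.37 in place of 0.58. Acute-phase genes had 6 members that rose, 2 that fell and 5 that did not pass, of 13. 9 rose and 2 fell when adjusted over the list alone. The fibrinogen chains FGG (643 ± 49.4 to 1027 ± 11.1 FPKM) and FGB (262 ± 18.2 to 407 ± 6.7 FPKM) rose, and IL6R, the interleukin-6 receptor, fell (7.199 ± 0.49 to 4.18 ± 0.17 FPKM). That list had a camera adjusted p of 0.0379 and an adjusted p of 0.569 with an estimated correlation, and its call was also lost with genes of at least 5 FPKM alone, with quantile normalization and without Dox 2 (adjusted p 0.159, 0.183 and 0.0619). Its median of 0.20 was 0.13 with quantile normalization and 0.21 without Dox 2, where the size of the rise did not fall.

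Hepatocyte transcription factors changed in both directions: of 19, 3 rose, 7 fell and 9 did not pass (list test adjusted p = 0.506). 3 rose and 7 fell when adjusted over the list alone. CEBPB (58.5 ± 2.6 to 111 ± 46.8 FPKM) and FOXA3 (21.3 ± 1.9 to 33.6 ± 1.5 FPKM) rose and NR2F2 fell (9.37 ± 0.61 to 7.28 ± 0.83 FPKM). The log2 fold change of CEBPB was 0.84, and 0.52 without Dox 2, and its call was lost with robust eBayes (adjusted p = 0.07). Of 8 gluconeogenesis genes, 4 rose, 0 fell and 4 did not pass (list test adjusted p = 0.0771, and 0.0198 to 0.125 over the alternatives, lowest with no filter, where the list passed), with the alanine aminotransferase GPT (4.66 ± 0.11 to 7.92 ± 0.27 FPKM) and the mitochondrial PCK2 (68.1 ± 2.4 to 91.1 ± 9.9 FPKM) higher. 4 rose and 0 fell when adjusted over the list alone. Fatty acid oxidation and ketogenesis had 10 members that rose, 2 that fell and 10 that did not pass, of 22 (list test adjusted p = 0.0771), with the carnitine carrier SLC25A20 (11.6 ± 1.3 to 17.99 ± 0.48 FPKM) and ACADVL (42.4 ± 2.7 to 60.1 ± 1.9 FPKM) higher. 10 rose and 2 fell when adjusted over the list alone. That list passed without Cont 1 (adjusted p = 0.0453) or without Cont 3 (0.0481), and its adjusted p reached 0.207 over the alternatives. Fatty acid and triglyceride synthesis had 3 members that rose, 9 that fell and 8 that did not pass, of 20 (list test adjusted p = 0.0771). 3 rose and 9 fell when adjusted over the list alone. ACLY, which makes cytosolic acetyl-CoA, fell from 118 ± 3.7 to 76.5 ± 4.3 FPKM, ACSS2 from 35.8 ± 0.76 to 23.01 ± 1.1 FPKM and the fatty acid synthase FASN from 318 ± 17.6 to 236 ± 15.7 FPKM. The synthesis list passed without Cont 1 (adjusted p = 0.0333), and its adjusted p reached 0.159 over the alternatives. Genes of cholesterol synthesis and uptake fell as a list, with 1 higher, 10 lower and 13 not past the test, of 24. 1 rose and 10 fell when adjusted over the list alone. HMGCS1 and LSS, enzymes of the pathway, fell from 81.9 ± 1.1 to 57.3 ± 2.5 FPKM and from 47.1 ± 0.68 to 33.9 ± 2.2 FPKM, and ACAT2, 52.3% of whose exonic length overlaps another gene, from 67.3 ± 0.59 to 45.997 ± 0.14 FPKM. The camera adjusted p was 0.0224 and the adjusted p with an estimated correlation 0.569. The median of -0.09 was -0.15 with quantile normalization, -0.13 after rescaling to reads outside the mitochondrial genome and -0.05 without Dox 2. Of 16 genes of bile acid and xenobiotic metabolism, 7 rose, 2 fell and 7 did not pass (list test adjusted p = 0.108), among them the nuclear receptor NR0B2, which represses bile acid synthesis (55.8 ± 0.42 to 89.6 ± 7.7 FPKM). 8 rose and 2 fell when adjusted over the list alone.

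Cytosolic ribosomal protein mRNAs rose. Of 77, 52 rose, 1 fell and 24 did not pass. 55 rose and 1 fell when adjusted over the list alone. RPL34 went from 81.1 ± 12.3 to 181 ± 23.7 FPKM. RPS27 went from 302 ± 28.6 to 625 ± 58.4 FPKM, RPS29 from 23.3 ± 1.96 to 48.4 ± 2.4 FPKM and RPL9 from 54.9 ± 5.6 to 113 ± 15.8 FPKM. The median was 0.25 (95% interval 0.19 to 0.31). The camera adjusted p was 7.02e-12 and the adjusted p with an estimated correlation 0.691. The median was 0.08 with quantile normalization, which still gave the list an adjusted p of 0.000204. The mean over the list varied among untreated libraries, at 0.11, -0.06 and -0.05 from the Cont mean in Cont 1, 2 and 3. It was 0.35, 0.33 and 0.31 above that mean in Dox 1, 2 and 3. These genes have processed pseudogenes, and how shared reads were counted is not given in the sources used here, so their levels are uncertain. Genes of ribosome biogenesis and MYC targets fell, with 2 higher, 19 lower and 12 not past the test, of 33. 2 rose and 19 fell when adjusted over the list alone. LYAR fell from 26.8 ± 0.53 to 17.4 ± 0.32 FPKM. The RNA polymerase I subunit POLR1A fell from 12.5 ± 1.2 to 8.55 ± 0.32 FPKM and nucleolin, NCL, from 157 ± 3.96 to 114 ± 1.1 FPKM. The list median was -0.18 (95% interval -0.23 to -0.05). Camera gave an adjusted p of 0.000232, and 0.569 with an estimated correlation. Nuclear genes for subunits of oxidative phosphorylation rose as a list, with 35 higher, 5 lower and 32 not past the test, of 72. 37 rose and 5 fell when adjusted over the list alone. Among the members with the largest changes, the complex IV subunits COX7B (16.4 ± 1.3 to 34.03 ± 2.5 FPKM) and COX7C (92.4 ± 11.3 to 172 ± 11.8 FPKM) and the complex III subunit UQCRB (10.6 ± 1.3 to 20.1 ± 0.79 FPKM) rose. All of these named members were also highest in Cont 1 among the untreated libraries. COX7C was at 105, 87.6 and 84.2 FPKM in Cont 1, 2 and 3. A trend of fold change on mRNA length was not tested for this list. This list's median was 0.15 (95% interval 0.09 to 0.28). Camera gave an adjusted p of 1.15e-05, and 0.699 with an estimated correlation.

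Mitochondrially encoded mRNAs were examined because doxycycline is known to bind mitochondrial ribosomes. Of 13, 0 rose, 4 fell and 9 did not pass, and the median was -0.32 (95% interval over members -0.38 to -0.28). Members varied together (estimated correlation 0.96) and the interval leaves out the spread between libraries, so it is too narrow. 0 rose and 0 fell when adjusted over the list alone. The list passed camera (adjusted p = 0.0288), but not with an estimated correlation (adjusted p = 0.865) or with fry (0.282 one way and 0.178 mixed). Its call was also lost with quantile normalization (0.151, median -0.04) and without Cont 2 (0.121), Dox 2 (0.167) or Dox 3 (0.0613), and its median without Cont 2 was -0.20. Quantile normalization sets the highest ranks to the same values in every library, so the loss there cannot show whether these abundant mRNAs fell. MT-CO2 had a log2 fold change of -0.40 (SE 0.13) and MT-ND6 of -0.39 (SE 0.13), and both calls were lost without Cont 2, Cont 3, Dox 2 or Dox 3. In those fits the changes were -0.30, -0.42, -0.31 and -0.39 for MT-CO2 and -0.27, -0.38, -0.31 and -0.35 for MT-ND6. They stayed close to the main values without Cont 3 or Dox 3. The call of MT-CO2 was also lost with no filter, in the fit with a replicate block and with quantile normalization (log2 fold change -0.05, with the same limit of that method). Their adjusted p over the alternatives ran from 0.0041 to 0.307 and from 2.83e-05 to 0.123. Of 75 mitochondrial ribosomal protein genes, 22 rose, 10 fell and 43 did not pass (list test adjusted p = 0.201), led by MRPL54 (29.7 ± 1.2 to 52.2 ± 4.2 FPKM). 22 rose and 10 fell when adjusted over the list alone. This list passed without Cont 1 (adjusted p = 0.0227), and its adjusted p reached 0.422 over the alternatives. Mitochondrial chaperones and proteases had 4 members that rose, 3 that fell and 10 that did not pass, of 17 (list test adjusted p = 0.708), with the protease HTRA2 higher (10.2 ± 0.504 to 13.8 ± 0.79 FPKM) and the chaperone HSPD1 lower (382 ± 4.6 to 317 ± 4.1 FPKM). 4 rose and 3 fell when adjusted over the list alone. The log2 fold change of HSPD1 was -0.27, and -0.48 with quantile normalization. Proteasome genes had 7 members that rose, 6 that fell and 18 that did not pass, of 31 (list test adjusted p = 0.997), with PSMD1 lower (32.2 ± 0.77 to 22.7 ± 0.82 FPKM) and PSMC6 higher (13.8 ± 1.6 to 18.5 ± 1.01 FPKM). 7 rose and 6 fell when adjusted over the list alone.

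Cytosolic heat shock genes fell, with 0 higher, 15 lower and 2 not past the test, of 17. 0 rose and 16 fell when adjusted over the list alone. HSPA8, the constitutive HSP70, fell from 323 ± 13.99 to 228 ± 38.8 FPKM and HSPH1 from 20.1 ± 0.096 to 14.6 ± 1.3 FPKM. HSPA1A, a near copy of HSPA1B, fell by 0.54, a call lost with robust eBayes and without Cont 3 (adjusted p = 0.0518 without Cont 3; 0.00107 to 0.0546 over the alternatives), and by 0.31 without Dox 2. The list had a median of -0.39 (95% interval -0.43 to -0.22). It had a camera adjusted p of 4.98e-06 and an adjusted p of 0.569 with an estimated correlation. Targets of NRF2, the regulator of antioxidant genes, fell as a list, with 3 higher, 13 lower and 8 not past the test, of 24. 3 rose and 13 fell when adjusted over the list alone. AKR1C2 fell, and TXN, thioredoxin, rose from 204 ± 19.02 to 331 ± 3.2 FPKM. AKR1C2 has close paralogs in AKR1C1 and AKR1C3. The camera adjusted p was 0.00534, the adjusted p with an estimated correlation 0.569, and the median of -0.27 was -0.17 without Dox 1. Of 6 metallothioneins and zinc transporters, 1 rose, 3 fell and 2 did not pass (list test adjusted p = 0.227), with MT1G lower (104 ± 3.95 to 79.1 ± 12.01 FPKM). 1 rose and 4 fell when adjusted over the list alone. Genes of ferroptosis and iron had 4 members that rose, 7 that fell and 8 that did not pass, of 19 (list test adjusted p = 0.774), with NCOA4, the ferritinophagy receptor (88.9 ± 2.5 to 137 ± 1.7 FPKM), and transferrin, TF (83.9 ± 2.7 to 118 ± 3.9 FPKM), higher. 4 rose and 8 fell when adjusted over the list alone. Replication-dependent histones had 2 members that rose, 1 that fell and 4 that did not pass, of 7 (list test adjusted p = 0.881), and their mRNAs mostly lack the poly(A) tail that the capture selects. 2 rose and 1 fell when adjusted over the list alone.

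Epithelial adhesion genes had 0 members that rose, 5 that fell and 14 that did not pass, of 19 (list test adjusted p = 0.28), with the claudin CLDN6 (36.1 ± 1.9 to 22.2 ± 0.37 FPKM) and KRT19 lower. 0 rose and 5 fell when adjusted over the list alone. Mesenchymal and matrix genes had 3 members that rose, 10 that fell and 9 that did not pass, of 22 (list test adjusted p = 0.0771). 3 rose and 10 fell when adjusted over the list alone. The lysyl oxidase LOX (5.12 ± 0.36 to 13.5 ± 2.3 FPKM) and SPARC (34.5 ± 0.76 to 50.5 ± 1.7 FPKM) were among the 3 that rose. The mesenchymal list passed with no filter (adjusted p = 0.0288) and without Cont 1 (0.0227), and its adjusted p reached 0.163 over the alternatives. Of 11 biliary and progenitor markers, 3 rose, 4 fell and 4 did not pass (list test adjusted p = 0.997), with KRT19 and SOX4 (-0.34) lower and LGR5 and GGT1 (0.44) higher. 3 rose and 4 fell when adjusted over the list alone. The lists of markers of other cell types had too few tested members for the list test. The 1 fibroblast marker tested, FBLN1, did not pass (-0.12, adjusted p = 0.168). Of 3 leukocyte markers, LYZ rose (75.5 ± 1.5 to 111 ± 4.1 FPKM), CORO1A fell (3.46 ± 0.35 to 2.66 ± 0.22 FPKM) and CD14 did not pass (-0.08). Of 2 endothelial markers, ESAM fell (3.23 ± 0.13 to 1.46 ± 0.34 FPKM) and PECAM1 did not pass (0.14). FBLN1, CD14 and PECAM1 were chosen after their values were seen. These counts were the same when adjusted over each list alone.

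Of the 42 lists with at least 5 tested members, 17 passed camera with a preset correlation, 10 higher and 7 lower. None passed with an estimated correlation, where 3 had an unadjusted p under 0.05 and the lowest adjusted p was 0.29. A loss there need not come from correlation, since that test also has only 4 residual degrees of freedom. Complement and coagulation had an estimated correlation of 0.013, near the preset 0.01, yet its unadjusted camera p went from 1.26e-07 to 0.00692. In the other 9 splits of the 6 libraries into 3 and 3, the preset correlation gave 9 to 16 lists. Each of those splits sets 2 libraries of 1 group and 1 of the other against the rest, so it keeps part of the difference between Dox and Cont and does not show what camera gives with no change. In 13 lists, none of them past the test, the median, the mean and the direction of the test did not all have one sign.

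**Figure D4:**
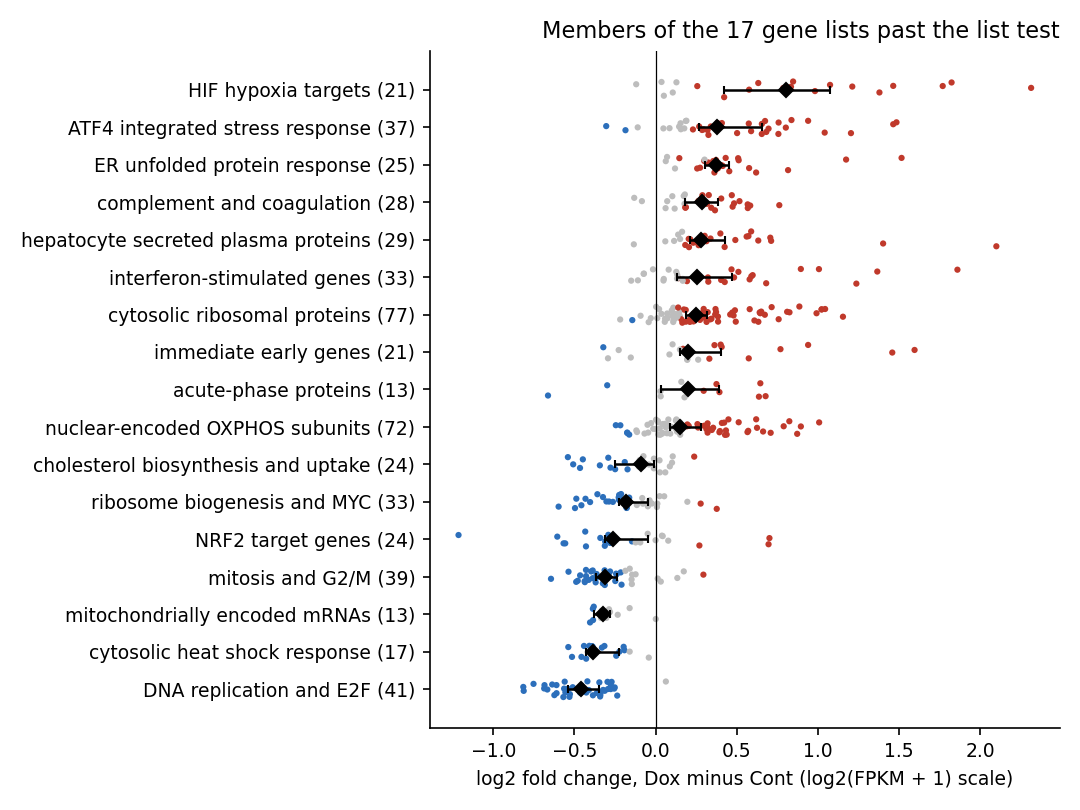
Log2 fold change (Dox minus Cont, log2(FPKM + 1) scale) of each tested member of the 17 gene lists past camera with a preset correlation, with the number of members in brackets; red members rose, blue members fell and grey members did not pass. Black diamonds are list medians with 95% bootstrap intervals over members, from -0.46 for DNA replication to 0.80 for the HIF targets.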

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

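The tests of Dox 2, of doxycycline itself, of copy number and of the scaling of abundant genes were chosen only after seeing the results. Rescaling to reads outside the mitochondrial genome was added after seeing the data. The intervals given here are over genes and leave out the spread between libraries.

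Genes under the limit of 1 FPKM had no part in the main test, and 280 of these 1267 passed when no limit was set, 154 of them higher and 126 lower with Dox. A change of at least 4-fold on the deposited log2 scale was found in 22, all higher, which is what drew attention to them. Log2 fold changes on that scale were 4.41 for MFSD2A, 3.81 for KIF1A, 3.77 for OASL, 3.77 for PRPH2, 3.16 for CLDN3, 3.10 for PCK1, 3.03 for P2RX1, 2.92 for NDUFA4L2, 2.80 for EGLN3, 2.79 for FBXL16, 2.64 for FOSB, 2.60 for IFIT2, 2.57 for BEST1, 2.54 for MEI1, 2.54 for TMEM151A, 2.53 for PNCK, 2.36 for FUT1, 2.33 for CP, 2.28 for COPZ2, 2.27 for CHAC1, 2.14 for OAS2 and 2.11 for FOS. The offset of about 2 reads per library in the deposited values lowers these fold changes, most at the lowest counts, and low counts carry a large counting error. PRPH2 had 4 reads over the 3 Cont libraries and 108 over the 3 Dox libraries.

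Ribosomal protein mRNAs rose by a median of 0.25 (log2). Removing the trend of fold change on gene length and GC content left 0.22 (95% interval 0.15 to 0.27), and rescaling to reads outside the mitochondrial genome left 0.20 (0.14 to 0.27). Both stayed above 0.5 of the value before, which argues against either this trend or the mitochondrial share as the whole cause. Length was that of all annotated exons joined (median 3109 bases over the list, 9845 for RPS29), not that of the mRNA. A trend on mRNA length was therefore not tested. Quantile normalization left 0.081 (0.00399 to 0.14). Ribosomal protein genes make up 27% of the 100 most abundant genes, so that method removes a shared shift of abundant genes whether technical or not, and the scaling of abundant genes and a real rise cannot be told apart by it. How reads shared with processed pseudogenes were counted was not tested.

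The hypoxia, ATF4 and endoplasmic reticulum stress lists rose by a median of 0.41 over their members. Without Dox 2, the library with the highest values, the median was 0.33 (95% interval 0.28 to 0.42), which argues against Dox 2 alone as the cause. Doxycycline itself stays open, since every Dox library had the drug and no library of drug-treated cells without the insert is among the 6. Mitochondrially encoded mRNAs, the products of the drug's known target organelle, had a median of -0.32 (-0.38 to -0.28), but -0.20 without Cont 2 and -0.04 with quantile normalization. That method sets the highest ranks to the same values in every library, so it removes a shift of these abundant mRNAs whether technical or not. The list call of these mRNAs was lost without Cont 2, with quantile normalization and with an estimated correlation. It was also lost without Dox 2 (median -0.23, adjusted p = 0.167) and without Dox 3 (median -0.30, adjusted p = 0.0613), the latter with a median close to that of all libraries. The effects of the drug and of RNF125 cannot be told apart by these libraries, since all 3 Dox libraries had both.

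Many genes changed by a small amount. A whole-chromosome copy number difference between the cultures would shift all genes of a chromosome, but the largest median of any autosome was 0.049, on chromosome 19 (95% interval 0.03 to 0.07), which argues against it. Of the 10 splits of the 6 libraries into 3 and 3, only the real one, 1 of 10, gave as many genes (4753, against at most 0 in the other splits). For gene lists, too, 1 of 10 splits gave as many (17, against at most 16). The other splits each mix both groups and keep part of the difference between them. With 10 splits the share cannot go under 0.1, too few for a share under 0.05. Induced RNF125, the drug and a difference between the cultures that was not recorded all remain open.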

How the results depend on the processing

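The deposited log2 values, voom on recovered reads and the rescaling outside the mitochondrial genome were chosen after seeing the data. With a 2-fold limit on the log2(FPKM + 1) scale, 89 genes were called, 83 higher and 6 lower, and at an adjusted p under 0.01, 2994 genes changed by Dox and 1349 genes lower with Dox passed, since both limits are stricter. With an estimated correlation 0 lists passed (3 at an unadjusted p under 0.05), and with fry 18 passed one way and 41 mixed, since fry asks another question. Mitosis, ATF4, immediate early and mitochondrially encoded genes passed camera but not fry one way (adjusted p 0.0517, 0.0849, 0.0832 and 0.282). The reverse held for RIG-I-like receptors, gluconeogenesis, fatty acid synthesis, fatty acid oxidation and bile acid metabolism (0.0311, 0.00286, 0.0132, 0.0229 and 0.0123). Leaving out each library in turn gave 3547 to 4607 changed genes, 1875 to 2373 higher and 1650 to 2242 lower, 15 to 21 lists, and an RNF125 log2 fold change of 3.57 to 3.72. Over all alternatives that change ran from 3.56 to 5.42, highest where low levels are damped least. The number of higher genes was 2144 with quantile normalization, where 1 called gene reversed and still passed, and 2008 with rescaling outside the mitochondrial genome. Leaving aside the stricter limits and the other list tests, 156 of the 179 named genes kept their side of the threshold under every alternative run, and 21 lost their call and 2 gained one under at least 1. The sign changed for 0 called and 3 uncalled named genes. Of the 42 tested lists, 34 kept their side of the threshold, 2 lost their call and 6 gained one under at least 1, and the median changed sign in 0 called and 11 uncalled lists. The causes were not tested. Robust eBayes was not run for lists.

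With the library number as a replicate block, 4835 genes (2463 higher, 2372 lower) and 17 lists passed and RNF125 changed by 3.67. Deviations of same-numbered Cont and Dox libraries correlated across genes, which are not independent replicates, at 0.13, 0.044 and 0.041. The other pairs ran from -0.12 (Cont 3 with Dox 1) to 0.061 (Cont 3 with Dox 2). These values are too small and too few to decide whether the numbers pair the libraries. In simulated data the fit called 20% of genes changed 1.2-fold and voom 50% of them, so small changes were missed there by either. Only 200 genes were changed in the simulation, against 4753 called in the data. Adjustment is stricter where fewer genes change, so these shares do not carry over to the data. Depth was not varied there.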

Other observations

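The test given here was chosen only after its pattern was seen. A rise in some genes of transport between the endoplasmic reticulum and the Golgi was noticed first. In a list of 39 such genes, coat proteins, cargo receptors and tethering factors, with the 4 genes that prompted it left out, 27 rose, 3 fell and 9 did not pass, with a median log2 fold change of 0.27 (95% interval 0.20 to 0.35). The list test with a preset correlation gave p = 5.79e-09 and with an estimated correlation p = 0.0124. YIPF5, SEC24A and TMED7 rose by 0.78, 0.72 and 0.72, and COPG2, TMED8 and YIPF1 fell. SEC24D is also in the unfolded protein response list. A rise across these genes may be present, which is a hypothesis, found and tested on the same libraries, and doxycycline itself stays open here too.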
